A study of Mus musculus with 133 samples.

How the data were processed

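The series held 133 mouse samples, of which 80 had a deposited peak list and 53 (24 inputs, 26 marks in cell lines and 3 marks in embryonic fibroblasts) had none. Mark, tissue and age came from the sample titles and tags, per the labels, and each combination of mark, tissue and age had 1 list. Per the labels, 64 lists came from pooled and filtered runs and 16 (8 for H3K4me3 and 8 for H3K4me1) named 1 lane. The software label named MACS for 62 lists, ELAND for 14, Bowtie for 2 and Peaks for 2, per the labels. Placenta carried the age label of 8 weeks, without a statement of whose age it is, and brown fat that of 24 weeks, per the labels.

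Reads of 36 cycles from Illumina sequencers of several models were aligned to mm9 with ELAND or Bowtie with a seed length of 25 and up to 2 mismatches, reads with 1 mapping location were kept, and clonal reads were discarded, per the series' design text. Peak caller settings, thresholds, tool versions and the use of input in calling are not given in the sources used here. The deposited lists give a position and a score per peak; the authors do not state the scale of the score, and it was used only to rank peaks within a list. From the values, the last 2 columns of each list are empty and were not used, nor were the name, display and strand columns, all H3K4me3 and H3K27ac peaks are 1000 bp wide, H3K4me1 peaks lie on a fixed grid except in thymus and olfactory bulb, where the width is constant, and the peaks of the other marks vary in width. The lists hold no read counts, so depth per list is unknown and precision was taken from the spread over tissue-stages. The series also has a table of read files, which was used only to count them: 29 samples had 2 read files and 1 sample had 1. All 16 lists labelled with 1 lane belong to samples with 2 read files, and how a list relates to these files is not stated.

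Peaks on chromosomes 1 to 19, X and Y were used; peaks on other sequences were left out. Intervals were handled with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9. An overlap was at least 1 bp in common. The count of H3K27ac peaks overlapping H3K4me3 was checked with bedtools 2.31.1, which gave the same number in 18 of 18 tissue-stages. The chance level was the mean of 20 circular shifts of a list within each chromosome, over the sequence from 3 Mb to the chromosome end, without Y. Distal H3K27ac peaks lay more than 2.5 kb from any H3K4me3 peak of the same tissue-stage. Sharing was the Jaccard index of merged peaks in bp, over the 18 tissue-stages with H3K4me3, H3K4me1 and H3K27ac. Genes were the 22367 protein-coding genes of GENCODE vM1 on NCBIM37 (mm9), and a promoter was the sequence within 1 kb of any annotated transcript start. Coordinates are counted from 1.

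The unit of each test was the tissue-stage. Paired differences were tested with a two-sided sign-flip permutation test, exact under 10 values and with 100000 resamples otherwise, and gene lists with 100000 random reassignments of lists to tissue-stages. The Benjamini-Hochberg adjustment ran over 12 planned tests with a threshold of 0.05. The E14.5 and chromosome X comparisons had no test. Shares on chromosome X have 95% Wilson intervals. Comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule was as follows. For a tissue gene list, the text names up to 4 members with the peak in the own tissue-stage and in the fewest others, and each member without it; this was applied to H3K27ac, and to H3K4me3 for lung, which has no H3K27ac list. For E14.5 against adult, it draws on the 10 protein-coding genes per direction with the largest difference in H3K27ac-covered sequence within 5 kb of the 5′ end. For H3K4me3 it draws on the 3 genes per tissue-stage with the widest peak relative to the others, and for H3K27me3 on the genes within the 10 widest regions found in the most tissue-stages. Because H3K4me3 peaks all have the same width, covered sequence within 5 kb of the 5′ end took the place of peak width in that rule, a change made after the widths were seen. The E14.5 genes are all named, apart from the histone genes, of which 1 per organ is named. The H3K4me3 genes are all named, and which of them have values in the text was chosen after the data were seen.

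The gene lists were liver, heart, kidney, cerebellum, cortex, olfactory bulb, embryonic brain, limb, lung, small intestine, B cell (assigned to spleen), thymocyte (thymus), granulocyte (bone marrow), macrophage (bone marrow-derived macrophages), brown fat, placenta, testis, erythroid (liver at E14.5), housekeeping genes and developmental regulators. Symbols were matched to the annotation directly or through the synonyms in the RefSeq gene table. Ptcra, Gfi1 and Sox1 had no match.

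The code was tested on simulated data with known answers. Planted shares of H3K27ac peaks at H3K4me3 peaks came back within 0.146 percentage points in 18 simulated pairs of lists. The exact test passed the threshold in 4.7% of 1000 simulated sets without a difference. In simulated gene lists with nothing planted, the difference was 1.64 percentage points (permutation p = 0.635).

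Alternatives fixed in advance were the stronger-scoring 50% of each list, the same number of strongest peaks in every list of a mark, an overlap of at least 50% of a peak, other distances and promoter windows, the share of overlapping peaks in place of the Jaccard index, autosomes only, pooled lists only, lists labelled with 1 lane only, and leaving out each tissue-stage in turn. Chosen after the data were seen were joining H3K4me1 peaks at most 1 kb apart, leaving out the lists of constant H3K4me1 width, leaving out testis, shifts of 50 to 500 kb, leaving out the widest H3K27me3 lists, and filtering the H3K27me3 lists alone. Motif counts used sequences of 8 bp in the central 300 bp of a peak against windows 2 kb to either side, CpG content used 500 bp windows against windows 5 kb to either side, neighbouring H3K27ac peaks at most 12.5 kb apart were joined to find the widest regions, and H3K9me3 in gene families was compared with 1000 shifts, a number raised from 20 after the values were seen to vary between runs.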

Results

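Histone modifications were mapped by chromatin immunoprecipitation and sequencing in tissues of C57BL/6 mice, and the regions enriched for each modification were deposited as peak lists on the mouse genome build mm9. Of 133 samples, 80 had a peak list: 19 for H3K4me3 and 19 for H3K4me1, 18 for H3K27ac, 10 for H3K27me3, 9 for H3K36me3, 2 each for H3K79me2 and H3K9ac, and 1 for H3K9me3. The lists covered 20 combinations of tissue and age, called tissue-stages here. Of the lists, 62 were labelled 8 weeks, 3 from brown fat 24 weeks, and 15 came from heart, liver, limb and whole brain of embryos at embryonic day 14.5 (E14.5). Placenta was among those labelled 8 weeks, and whether this is the age of the mother is not stated. Each mark had 1 list per tissue-stage, so there were no replicates within a group, and every spread and p below is over tissue-stages. The lists carry no read counts, so the sequencing depth behind each list is unknown. The other 53 samples, 24 inputs, 26 marks in cell lines and 3 marks in embryonic fibroblasts, had no peak list and were not analysed here.

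H3K4me3 covered less sequence than H3K4me1 in 19 of the 19 tissue-stages with both marks. H3K4me3, which marks promoters, gave between 14843 peaks in placenta and 42860 in testis, and a median of 66.8% of its covered sequence lay within 1 kb of a transcript start of a protein-coding gene. H3K4me1, which marks enhancers and the flanks of promoters, gave 64582 peaks in thymus to 157265 in testis, with a median of 11.6% of covered sequence at starts. H3K27ac, found at active promoters and enhancers alike, gave 12682 peaks in thymus to 49288 in placenta. H3K36me3, laid down in transcribed gene bodies, had a median of 85.0% of its covered sequence in protein-coding genes more than 1 kb from a start. A median of 10.6% lay within 1 kb of a start. H3K27me3, the mark of Polycomb repression, varied most in extent, from 0.167 Mb in CD43-negative B cells to 33.5 Mb in liver.

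**Figure D1:**
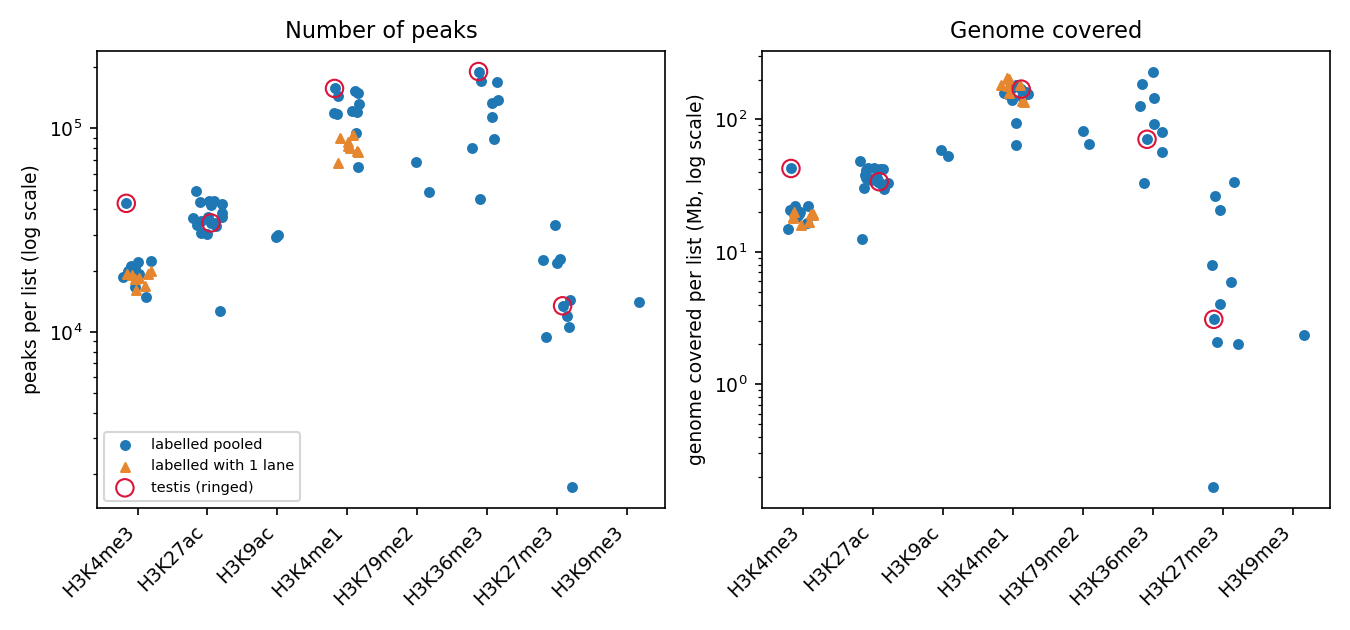
Number of peaks (left) and megabases covered (right, both on log axes) for each of the 80 lists by mark; circles are lists labelled pooled, triangles lists labelled with 1 lane, and testis is ringed. Testis had 42860 H3K4me3 peaks, more than any other list of that mark, and H3K27me3 spanned 0.167 to 33.5 Mb.

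H3K4me1 peaks outnumbered H3K4me3 peaks in 19 of 19 tissue-stages, by a mean log2 ratio of 2.38 ± 0.38 (SD, n = 19; two-sided permutation p = 1e-05, the smallest the resamples can give; 1.5e-05 after Benjamini-Hochberg adjustment over the 12 planned tests). The excess was widest in placenta (log2 ratio 3.28) and limb at E14.5 (2.98), and narrowest in testis (1.88) and thymus (1.95), but its size depends on how finely a list is cut: the smallest gap between H3K4me1 peaks was 1100 bp in each list labelled with 1 lane and 100 bp in most pooled lists. With H3K4me1 peaks at most 1 kb apart joined, the ratio was 2.65 in placenta, 2.47 in limb, 1.94 in thymus, 1.75 in brown fat and 1.34 in testis. The median width of H3K4me1 peaks relative to H3K4me3 peaks had a mean log2 ratio of -0.04 ± 0.26 (n = 19; permutation p = 0.521, adjusted 0.521), with H3K4me1 wider in 6 of 19 tissue-stages. All H3K4me3 and H3K27ac peaks were 1000 bp wide, so that comparison measured H3K4me1 widths against a constant, and its direction turned with the lists used. On the stronger-scoring part of each list the mean was 0.62 (permutation p = 1e-05, the smallest possible) and with H3K4me1 peaks joined it was 0.16 (permutation p = 0.00301), but in pooled lists alone it was -0.19 (permutation p = 0.00738).

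Active promoters and active enhancers both carried H3K27ac, and in most tissues the larger part of it lay away from promoters. In testis 49.3% of H3K27ac peaks touched an H3K4me3 peak of the same tissue, followed by 41.6% in bone marrow and 41.2% in bone marrow-derived macrophages. Placenta had the lowest share, 18.6%, and there 75.1% of H3K27ac peaks lay more than 2.5 kb from any H3K4me3 peak. List size bears on both extremes. Placenta had the fewest H3K4me3 peaks (14843) and the most H3K27ac peaks (49288), and testis the most H3K4me3 peaks (42860). Shifted lists gave 1.22% in placenta and 3.32% in testis, and the order of tissues was not separated from list size. Nearly all distal H3K27ac, more than 2.5 kb from H3K4me3, lay within H3K4me1 in macrophages (98.2%), liver at E14.5 (95.4%) and adult heart (94.4%). The lowest shares came from olfactory bulb (53.2%) and thymus (56.2%), the tissue-stages whose H3K4me1 peaks all had the same width.

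Over 18 tissue-stages, 33.6% ± 6.86 (SD) of H3K27ac peaks overlapped H3K4me3 by at least 1 bp, against 1.64% ± 0.447 for lists shifted at random along the chromosomes. The difference was 31.99 ± 6.59 percentage points and was above 0 in 18 of 18 (two-sided permutation p = 1e-05, the smallest possible; adjusted 1.5e-05). Distal H3K27ac peaks, 58.8% ± 8.29 of the total, overlapped H3K4me1 in 85.4% ± 12.7 of cases against 10.3% ± 1.74 for shifted lists. This difference was 75.03 ± 11.6 points, again in 18 of 18 (permutation p = 1e-05, the smallest possible; adjusted 1.5e-05).

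**Figure D2:**
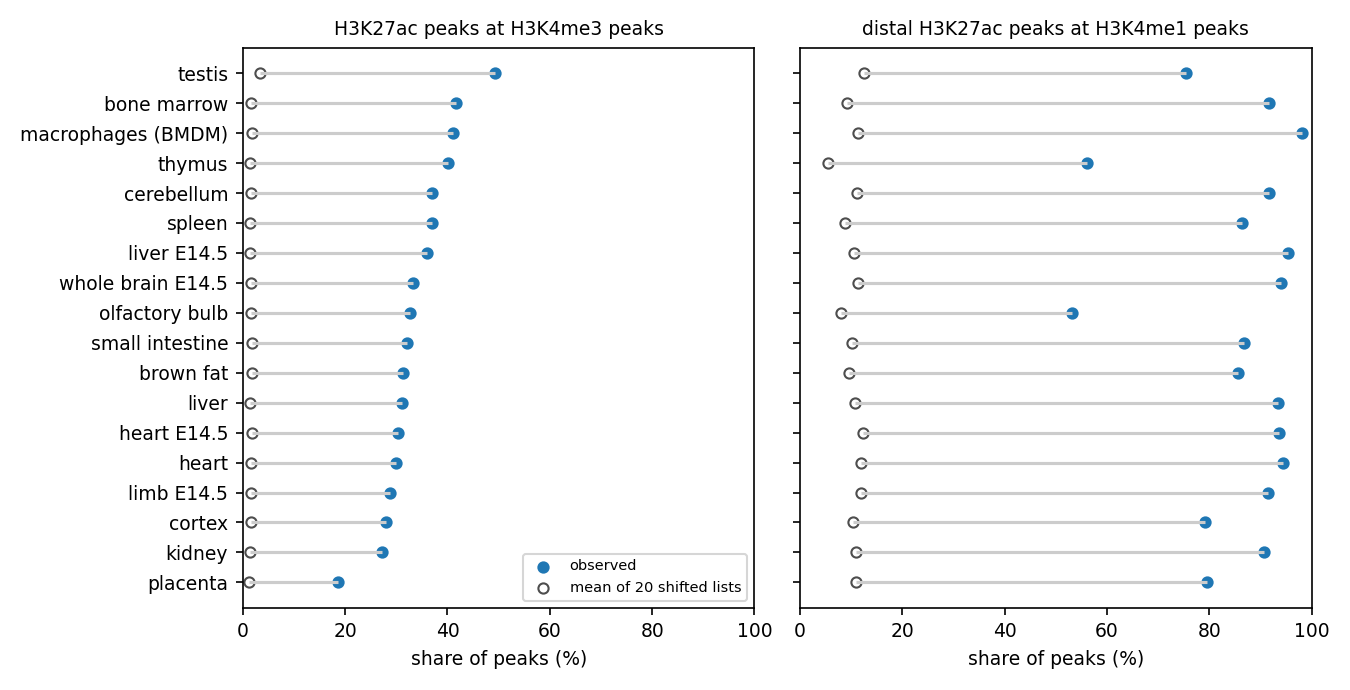
Share of H3K27ac peaks that overlapped an H3K4me3 peak (left) and share of distal H3K27ac peaks that overlapped an H3K4me1 peak (right) in each of 18 tissue-stages (filled circles), with the mean of 20 randomly shifted lists (open circles), in percent. The observed share exceeded the shifted one in 18 of 18 tissue-stages in both panels.

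H3K4me3 overlapped more between tissues than distal H3K27ac did. Of 69210 merged H3K4me3 regions, 8778 (12.7%) were marked in all of 18 tissue-stages, as were 8510 (2.68%) for H3K4me1, 2001 (0.957%) for H3K27ac and 3 of 174714 for distal H3K27ac, whose definition leaves out regions near H3K4me3 and so sets part of that count. Regions marked in 1 tissue-stage alone made up 53.9% for H3K4me3, 44.7% for H3K4me1 and 58.0% for distal H3K27ac. Without testis these shares were 36.8%, 44.2% and 58.2%. Distal H3K27ac of bone marrow was nearest to that of spleen (Jaccard index 0.178) and cortex to olfactory bulb (0.136), organs with related cells, but also brown fat to heart (0.204), kidney to liver (0.139), placenta to kidney (0.0924) and testis to heart (0.0712). Limb at E14.5 had the most widely shared H3K4me3 (mean Jaccard index with the other tissue-stages 0.484) and testis the least shared (0.259).

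The mean Jaccard index in bp with the other tissue-stages was 0.434 ± 0.0536 (SD, n = 18) for H3K4me3, 0.203 ± 0.0360 for H3K4me1, 0.153 ± 0.0228 for H3K27ac and 0.0582 ± 0.0151 for distal H3K27ac. H3K4me3 exceeded H3K4me1 by 0.231 ± 0.0619, H3K27ac by 0.281 ± 0.0580 and distal H3K27ac by 0.376 ± 0.0514, each in 18 of 18 tissue-stages (two-sided permutation p = 1e-05 for each, the smallest possible; adjusted 1.5e-05). The values of a mark share lists with one another, which makes these p approximate.

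**Figure D3:**
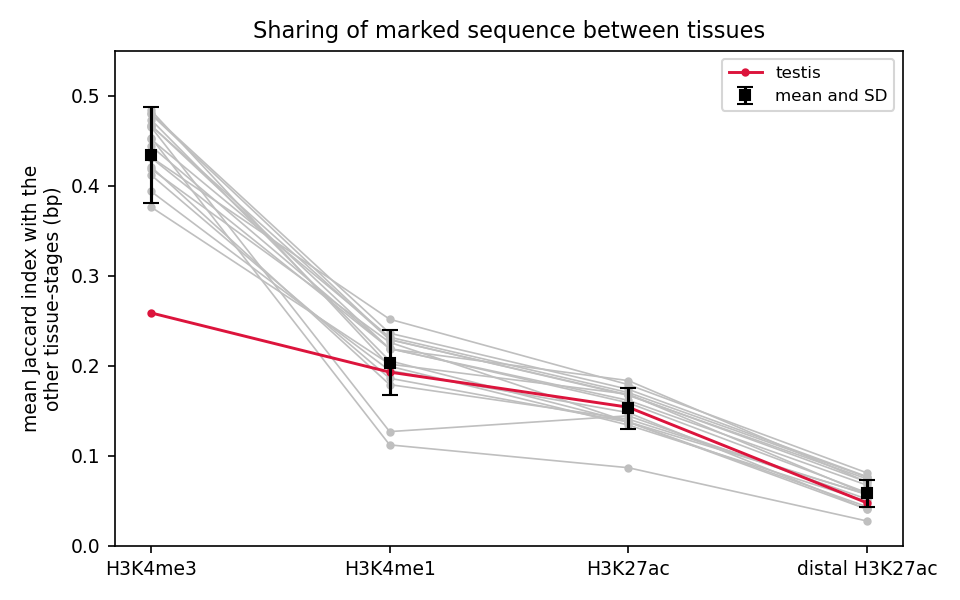
Mean Jaccard index (in bp) of each of 18 tissue-stages with the others, by mark; lines join the values of a tissue-stage, red marks testis, and squares with bars give the mean and SD. The mean fell from 0.434 for H3K4me3 to 0.0582 for distal H3K27ac.

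Genes that define a tissue carried H3K27ac at their promoters in that tissue more often than in the others. In liver, 11 of 13 hepatocyte genes had a promoter peak, among them Cyp7a1 (bile acid synthesis), Cps1 (urea cycle), Fgb (fibrinogen) and Tat, each with 0 of 17 other tissue-stages marked; Apoa1 and Apoa2 had none in liver. In small intestine, 11 of 12 epithelial genes were marked, including the lineage regulators Cdx1 and Cdx2 and the brush border enzymes Lct and Sis, with Apoa4 the exception. Limb at E14.5 had the peak at 11 of 12 genes, including Hoxd13, Hoxa13, Tbx4 and Msx2 but not the cartilage gene Acan. In testis, 11 of 12 genes were marked, including the sperm chromatin genes Prm1, Prm2 and Tnp1 and the acrosomal gene Acr, but not Tnp2. Cortex was marked at 10 of 10 genes, with Slc17a7 marked nowhere else and Neurod6, Tbr1 and Foxg1 in 1 other tissue-stage each.

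Gene lists of blood cells were marked in their own tissue-stage and, to differing extents, in others. Bone marrow had H3K27ac at 10 of 11 granulocyte genes, with Ltf, Ngp and Ctsg marked in no other tissue-stage, Mpo in 1 other, and no peak at Elane; liver at E14.5 had 7. In spleen 8 of 10 B-cell genes were marked, led by Cr2, Spib, Cd79a and Ms4a1, without Cd19 and Cd79b, and bone marrow had as many. In macrophages 9 of 11 genes were marked, led by Mmp12, Cd68, Lyz2 and Itgam, without Csf1r and Mpeg1, and brown fat also had 9, bone marrow 8, adult liver 7, small intestine and testis 6 each, and spleen 5. In thymus 9 of 13 thymocyte genes were marked, led by Cd4, Rag2, Themis and Cd3e, without Cd3g, Cd8a, Cd8b1 and Tcf7, against 10 in bone marrow and 9 in spleen. The thymus list was the shortest, though, and marked 18.5% of all promoters, against 48.7% in bone marrow and 47.5% in spleen. These counts are therefore not on an equal footing. Erythroid genes were marked at 10 of 12 promoters in liver at E14.5, the organ of fetal blood formation, led by Hba-a1, Hbb-b1, Alas2 and Gypa, without Ank1 and Hemgn, and at 12 of 12 in bone marrow.

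In kidney 9 of 12 genes were marked, with Umod, Slc12a1, Cdh16 and Slc22a6 marked in no other tissue-stage, but not the podocyte genes Nphs1 and Nphs2 nor Slc12a3. In heart 10 of 14 were marked, led by Myh6, Actc1, Tnnt2 and Myl3, without Pln, Nkx2-5, Tbx5 and Hand2, against 12 in heart at E14.5. In cerebellum 7 of 11 were marked, led by Pvalb, Gabra6, Barhl1 and En2, without the Purkinje cell genes Pcp2 and Calb1, and without Zic1 and Neurod1. In olfactory bulb 6 of 10 were marked, led by Sp9, Dlx1, Sp8 and Dlx5, without Dlx2, Tbx21, Th and Eomes, against 7 in whole brain at E14.5. In whole brain at E14.5 7 of 10 were marked, led by Neurog2, Sox2, Ascl1 and Pax6, without Nes, Hes5 and Elavl3, against 8 in adult cortex and 7 in olfactory bulb. Brown fat had 8 of 13, led by Plin1, Cidea, Dio2 and Cpt1b, without Ucp1, Adipoq, Elovl3, Cox8b and Fabp4, against 7 in adult heart. Placenta had 7 of 12, led by Tpbpa, Prl3b1, Tfap2c and Hand1, without Prl3d1, Gcm1, Elf5, Phlda2 and Ascl2. A list of 12 housekeeping genes had between 6 promoters marked, in thymus, and 12.

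For 17 gene lists written in advance, a mean of 77.9% of members had H3K27ac in their own tissue-stage against 15.7% in the others, a difference of 62.3 ± 15.2 percentage points (SD) that was above 0 for 17 of 17 lists (two-sided permutation p = 1e-05, the smallest possible; adjusted 1.5e-05). The own tissue-stage ranked first for 10 of 17 lists, with every tie counted against it. For the B-cell and macrophage lists it was tied for the highest share. For H3K4me3, 18 lists, lung included, gave 84.5% against 34.1%, a difference of 50.4 ± 19.1 points in 18 of 18 (permutation p = 1e-05, the smallest possible; adjusted 1.5e-05). There the own tissue-stage ranked first for 10 of 18, with embryonic brain at rank 8 and macrophage and placenta at rank 4. Ties were again counted against it. Cerebellum (100%) alone exceeded the 90% of embryonic brain, and adult heart (90.9%) alone the 81.8% of macrophage. The placenta, cortex, olfactory bulb, brown fat and erythroid lists were tied for the highest share. Lung had H3K4me3 at 8 of 10 genes, with Sftpa1, Sftpb, Scgb1a1 and Ager marked in no other tissue-stage, and without Sftpc and Sftpd, but on the stronger-scoring part of the list the share was 30%.

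**Figure D4:**
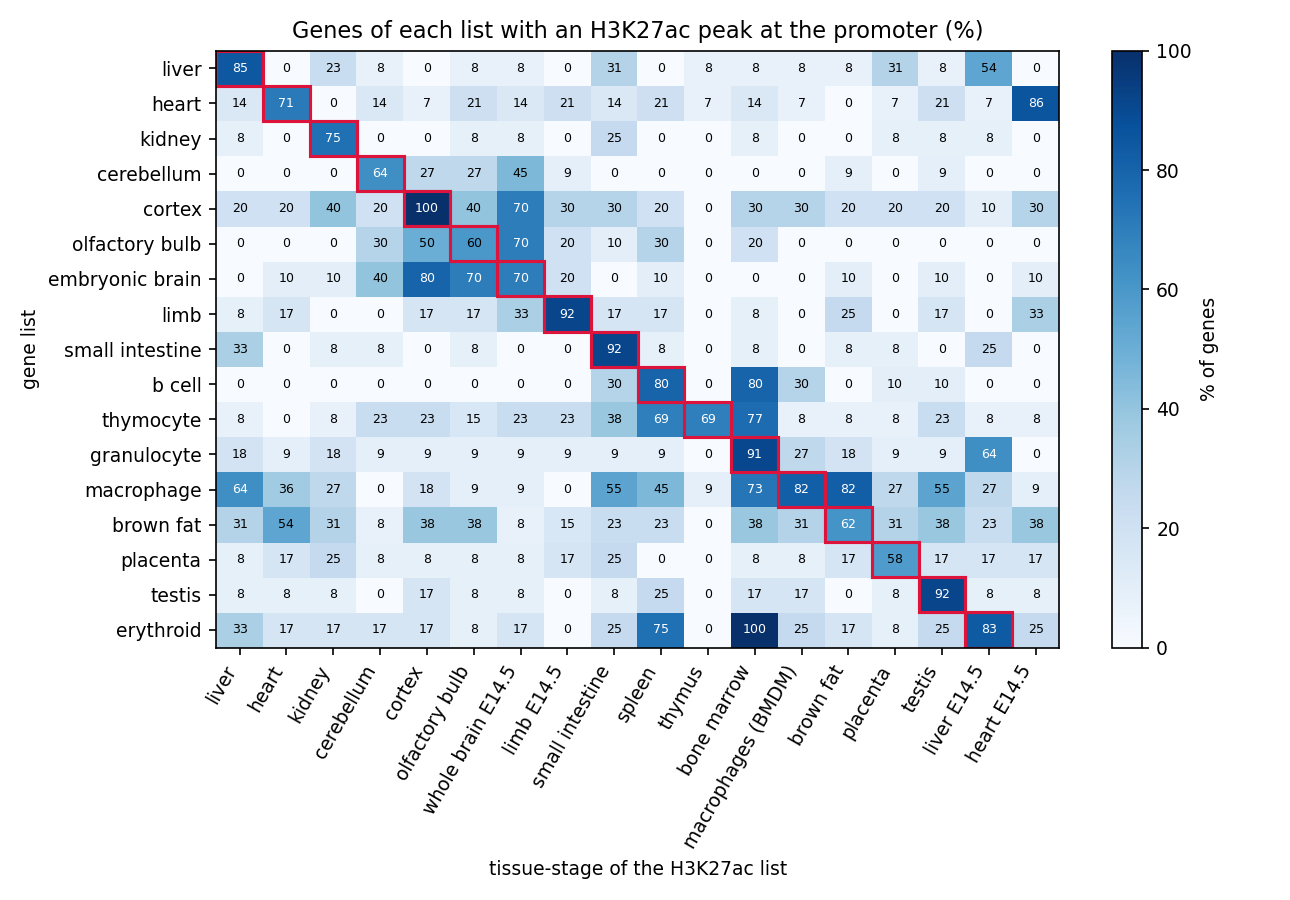
Percent of the genes of each list (vertical axis) with an H3K27ac peak within 1 kb of a transcript start, in each of 18 tissue-stages (horizontal axis); red frames mark the tissue-stage each list was written for. The framed cells range from 58.3% for placenta to 100% for cortex, with a mean of 77.9%.

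The genes over which H3K4me3 spread farthest, relative to the other tissue-stages, included several known from the tissue. In liver it covered 3912 bp around the start of Cyp7a1 and 3000 bp at the major urinary protein gene Mup3, with 0 bp elsewhere. In testis it covered 4655 bp at Gtsf1, a factor of germ cell transposon silencing, against 0 bp in the other tissue-stages. Macrophages had 5000 bp at the innate immune receptor gene Tlr13 (highest other value 1000 bp), placenta had 4624 bp at the trophoblast regulator Hand1 (2578 bp), and bone marrow had 4000 bp at the heme synthesis gene Alas2 (1000 bp). Adult heart had 2000 bp at Murc and 3000 bp at Myoz2, and heart at E14.5 had 2000 bp at the fetal myosin gene Myh7. Whole brain at E14.5 had 3000 bp at the hypothalamic regulator Otp, kidney 2587 bp at the tight junction gene Cldn16, lung 3000 bp at Lamp3, and small intestine 2354 bp at the lactase gene Lct. The measure also picked genes with no evident tie to the tissue, such as Cdc40 (3000 bp), Gm11696 and Gna13 (4000 bp) in cortex, 4930524J08Rik and Hnrnpd (4283 bp) in macrophages, and Gm10123 (4000 bp) beside Lilrb3 (3119 bp) in bone marrow. The remaining genes it picked were Gm4922 and Rnf133 in testis, Shisa6, Gria4 and Sema4f in cerebellum, Npffr2, Cpa6 and Kcnd3 in olfactory bulb, Hoxb3 and Foxb1 in whole brain, Hoxc10, Acan and 9630014M24Rik in limb, Rbm20 and Cacna1d in heart at E14.5, Lum in adult heart, Tubb1, Hbb-b2 and Hist1h1b in liver at E14.5, Akr1c14 in adult liver, Akr1c21 and Amacr in kidney, C7 and Mbip in lung, Crlf2 and Bbc3 in placenta, Slc28a1 and 9130404H23Rik in small intestine, Ccr6, Gpr174 and 5830405N20Rik in spleen, A930002I21Rik, Adam12 and Arl5c in thymus, and A530053G22Rik, Ankrd5 and BC034902 in brown fat. These values are sequence covered within 5 kb of the gene's 5′ end, in lists whose peaks have a fixed width.

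The comparison of E14.5 with adult organs asked how chromatin changes as organs mature. The embryonic liver, which forms blood, had H3K27ac over 5000 bp near the start of the globin gene Hba-a2, 4542 bp at Hbb-b1, 4662 bp at Dlk1, 5465 bp at the fetal serum protein gene Afp and 4205 bp at the proliferation gene Mki67. Adult liver had 0 bp at these genes except 818 bp at Afp. Adult liver in turn had 5901 bp at Cyp2e1, 5688 bp at Cyp7a1 and 4622 bp at Mup3, against 0 bp at E14.5, and 6726 bp at Alb against 1574 bp. In heart, E14.5 had 4345 bp at Bmp10, a growth factor of the developing ventricle, 3611 bp at Sall1 and 3246 bp at the BMP antagonist Nog, all at 0 bp in the adult. Adult heart had 4000 bp at the fatty acid transporter gene Cd36 and 4000 bp at Timp4, both at 0 bp in the embryo. The other genes with the largest differences were Gm17669, Bex4 and Chsy1 for liver at E14.5, Kng2, Akr1c6, Lamp2, Clec2d, Gm4951 and Enpp3 for adult liver, Ttyh3 and Frs2 for heart at E14.5, and Pcdh19, Tbc1d10a, Cyp4b1, Nepn, Clec2d, Nav3, Gm17438 and Ecm2 for adult heart. Histone genes were among those with more H3K27ac at E14.5 in both organs (Hist1h2bh in liver, 5605 bp against 0; Hist1h2an in heart, 3946 bp against 0).

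Of 22367 protein-coding genes, 3717 had more H3K27ac at E14.5 and 3804 more in the adult in liver, and 3402 and 2945 in heart. In H3K27ac, heart at E14.5 was nearer to adult heart than to any of the other 13 adult tissues, placenta counted among them by its label (Jaccard index 0.289), and whole brain at E14.5 was nearest to olfactory bulb (0.204). Liver at E14.5 was nearer to bone marrow (0.235) than to adult liver (0.205, rank 3 of 14), a rank between 2 and 4 under the alternatives. In distal H3K27ac alone, however, it was nearest to adult liver (0.108). Of the erythroid promoters, 10 of 12 were marked in the embryonic liver against 4 of 12 in the adult liver. In H3K4me3, adult heart ranked 9 of 15 for heart at E14.5, and olfactory bulb 1 for whole brain. Adult liver ranked 2 of 15 for liver at E14.5, a rank that moved to 1 with the same number of strongest peaks from every list and to 10 with the share of overlapping peaks in place of the Jaccard index. The E14.5 lists were labelled pooled, while the H3K4me3 and H3K4me1 lists of adult heart and liver were labelled with 1 lane. In H3K4me1 the adult organ ranked 1 for both heart (0.338) and liver (0.293), the latter 2 under each of 3 alternatives, and whole brain at E14.5 was nearest to testis (0.248). Of the E14.5 H3K27ac peaks, 44.2% in heart and 53.1% in liver had no overlap in the adult organ. With 1 list per organ and age, these comparisons have no test.

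Polycomb-marked chromatin sat on developmental regulators in most tissue-stages. The 10 widest H3K27me3 regions found in 10 of 10 tissue-stages held homeobox and related genes: Hoxa10, Hoxa11 and Hoxa13 (chromosome 6: 52188968 to 52228474, 39.5 kb at the widest), Pitx2, Nkx2-3, Pax3, Barhl2, Hoxd3 to Hoxd10, Lbx1, Hoxb13, Six3 and En1. Each was widest in whole brain at E14.5, where 95.2% to 100% of it was covered, against a median over tissue-stages of 20.9% to 44.4%. With regions at most 5 kb apart joined, the 10 widest kept Lbx1, Pax3, Hoxb13 and, as larger regions, the Hoxa cluster with Evx1 and the Hoxd cluster with Evx2. The others were then the Hoxc cluster (269 kb, the widest), Foxd2 with Foxe3, Nr2e1, Foxe1 and a region without a gene. Of the joined regions, Foxd2 with Foxe3, Lbx1 and Foxe1 were most covered in liver (44.2% to 48.6%), Nr2e1 (59.2%) and the region without a gene (60.6%) in heart, and the rest in whole brain at E14.5. Among the developmental regulators listed in advance, H3K27me3 was missing from Gata6 in heart, from Gata6 and Foxa2 in liver, from Pax8, Tbx3 and Cdx2 in small intestine, and from Shh and Isl1 in testis. In kidney it was missing from Hoxa9, Hoxb1, Hoxb9, Hoxc10, Hoxd10, Pax2, Pax8, Shh, Irx3 and T, in cerebellum from Hoxb1, Hoxd12, Pax6, Pax8, Lhx3, En2 and Eomes, and in thymus from Tbx5, Shh, Six2, Dlx5 and Isl1. The kidney and cerebellum lists marked only 7.05% and 6.34% of all promoters, though, against 14.66% in heart and 16.96% in liver. The numbers of genes without the mark are therefore not on an equal footing, and tissue was not separated from list size.

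Of 58 developmental regulators listed in advance, a mean of 86.6% ± 25.0 (SD, n = 10) had H3K27me3 within 1 kb of a start, against 12.6% ± 6.32 of all protein-coding genes. The difference was 73.9 ± 20.6 percentage points and above 0 in 10 of 10 tissue-stages (two-sided permutation p = 0.00196; adjusted 0.00261). Spleen and whole brain at E14.5 had the mark at 58 of 58, heart at 57, and B cells at 10. With the B cells set aside, 35 of the 58 carried it in each of the other 9 tissue-stages, as did 376 of 22367 protein-coding genes.

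H3K27me3 avoided H3K36me3 and met H3K4me3. The avoidance was deepest in spleen (log2 observed over shifted overlap -4.02) and liver (-3.82) and shallowest in whole brain at E14.5 (-0.75). The overlap with H3K4me3, the combination known as bivalent chromatin, was highest in spleen (log2 5.38) and thymus (5.08), and lowest in liver (2.70). In whole brain at E14.5, 33.0% of H3K4me3 peaks touched H3K27me3, against 5.08% in cerebellum, but their H3K27me3 lists covered 26.2 and 2.02 Mb, and relative to shifted lists the log2 ratios were 4.79 and 4.50. A tissue holds several cell types, so an overlap of lists does not show that both marks sit on the same chromosome copy.

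Across 9 tissue-stages the overlap of H3K27me3 with H3K36me3 was below that of shifted lists in 9 of 9, by a mean log2 ratio of -2.61 ± 1.19 (SD; two-sided exact permutation p = 0.00391, the smallest this number allows; adjusted 0.00426). The overlap with H3K4me3 was above that of shifted lists in 9 of 9, by 4.45 ± 0.84 (exact permutation p = 0.00391, the smallest possible; adjusted 0.00426). When each list was restricted to its stronger-scoring part, the overlap with H3K4me3 had a mean log2 ratio of 1.38 and no longer passed the threshold (exact permutation p = 0.145). With the H3K27me3 lists alone so restricted, the mean was 4.25 (exact permutation p = 0.00391, the smallest possible).

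Chromosome X in testis, where the sex chromosomes are silenced in meiotic germ cells, stood apart for H3K36me3 and, less far, for H3K27ac. H3K36me3 was almost absent from it: 13 of 190482 peaks (0.00682%, 95% Wilson interval 0.00399 to 0.0117) lay there, against 0.835% in kidney to 3.03% in liver. The X promoters themselves were marked, with H3K4me3 and H3K27ac together at 450 genes in testis against 158 in thymus to 357 in whole brain at E14.5. Of those 450 genes, 8 (1.78%) had an H3K36me3 peak in the gene, compared with 74.9% of 11034 such autosomal genes in testis and with 59.3% of X genes in kidney to 82.6% in liver.

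Testis had the highest X share of H3K27ac peaks, 3.73% (3.54 to 3.94) against 1.65% in bone marrow to 3.16% in macrophages. It had the lowest X share of H3K4me3 peaks, 2.32% (2.18 to 2.47) against 2.75% to 3.46%. On the stronger-scoring part of the lists the testis share of H3K4me3 was 3.30%, which ranked 9 of 19, while H3K27ac kept its rank of 1 and H3K36me3 its rank of 9 of 9. For H3K4me1 testis ranked 5 of 19 (1.99%, 1.92 to 2.06), and for H3K27me3 9 of 10 (0.573%, 0.459 to 0.715). The intervals cover counting error only, and with 1 testis list per mark no test was made.

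**Figure D5:**
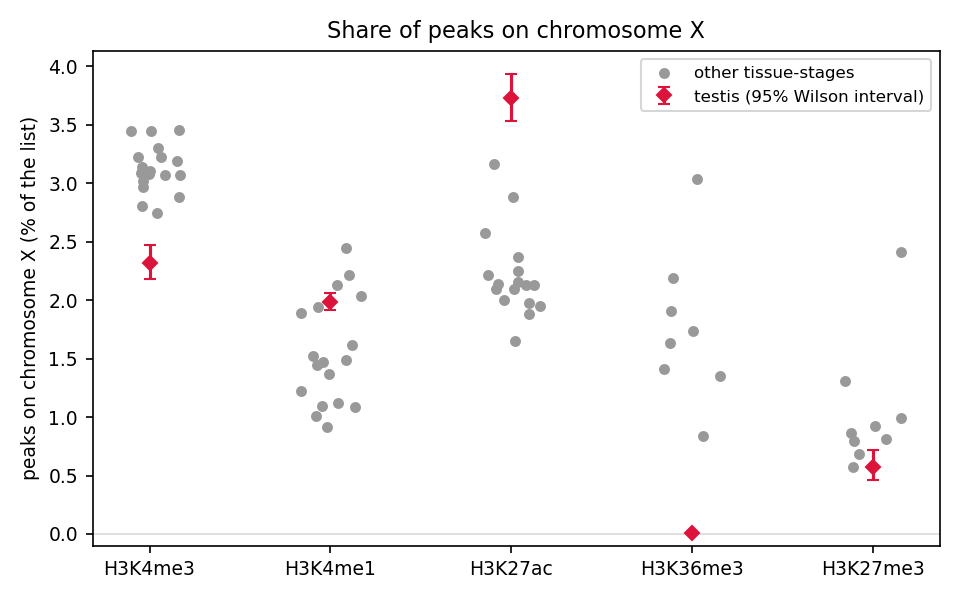
Percent of the peaks of each list that lay on chromosome X, by mark; gray points are the other tissue-stages and red diamonds testis with its 95% Wilson interval. Testis H3K36me3 lay at 0.00682%, against 0.835% to 3.03% in the other tissue-stages.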

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

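Chosen only after the result was seen were the tests on the strongest testis H3K4me3 peaks, on H3K27ac at testis-only peaks, alone and at matched score, the 3 tests on chromosome X in testis, the test of the B-cell list against spleen, and the lookups in H3K9me3, H3K9ac and H3K79me2; the CpG test and the test of nesting in the widest H3K27me3 lists were written before. The test of the B-cell list replaced an earlier one whose value, a median percentile of 56.6, fell between its bounds, and its bound was changed again once the strongest peaks of the other lists had been seen; the bound for H3K27ac was also changed after its value was seen, and the test at matched score was split into 2 parts after its gaps were seen.

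Values far from the others by Dixon's gap rule came up in 2 of the 9 sets tested, and chance flags about 1 in 20 such sets; the members of a set are tissue-stages, not replicates. The X share of H3K27me3 peaks in whole brain at E14.5 was 2.41%, far above the other 9 tissue-stages. This was the only E14.5 list of the mark. The H3K27ac list of the same tissue-stage, with the sex label not determined, had a peak at the Xist promoter, and the H3K4me3 list had none. Stage, sex and tissue therefore cannot be told apart here. The excess of H3K27me3 at developmental regulators in CD43-negative B cells was 15.8 percentage points, far below the others, in a list of 1730 peaks. As a ratio it was not low: 17.2% of the regulators against 1.47% of all promoters, 11.8 times, below cerebellum (13.9 times) alone.

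Marks that no comparison of the report used gave signals above shifted lists. H3K9me3 in whole brain at E14.5 covered numbered zinc finger (Zfp) genes at a log2 of observed over shifted overlap of 4.14 and clustered protocadherins at 6.49. H3K9ac in H3K4me3 regions had a log2 ratio of 5.15 in heart and 5.31 in liver. H3K79me2 in H3K36me3 regions had 2.79 in heart and 1.87 in liver. With 1 or 2 lists per mark, none of these was tested.

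Of 42860 testis H3K4me3 peaks 21965 (51.2%) had no overlap in another tissue-stage, and a looser threshold does not account for all of them, since 25.4% of the strongest 14843 peaks were testis-only against at most 4.26% in the other lists at the same number. CpG-rich promoters missing from the annotation do not account for those far from annotated starts, whose median observed over expected CpG was 0.245, nearer to their flanks (0.180) than to shared peaks at starts (0.758), but testis-only peaks at annotated starts had 0.236, so this says nothing against CpG-poor promoters. Active elements with H3K27ac cannot be told apart from another origin: 18.8% of testis-only peaks had H3K27ac, against 59.2% of shared testis peaks and a median of 60.8% of peaks found only in 1 tissue-stage elsewhere, but placenta had as low a share (18.1% of 155 peaks). The share was also compared at matched H3K4me3 score. In the stronger 5 of 10 score groups (7610 testis-only peaks) it differed from that of shared testis peaks by a mean of -24.4 percentage points. A low H3K4me3 score alone therefore does not account for the gap there. The groups matched score but not place: 76.4% of testis-only peaks lay far from annotated starts, against 25.5% of shared testis peaks. A loss of weak H3K27ac peaks is thus not excluded in the stronger groups. In the weaker 5 groups (14355 peaks), at a mean of -11.2 points, such a loss cannot be told apart from a lack of H3K27ac either. The share was lower in 10 of 10 groups. The gaps of -8.69 and -9.35 points in the 2 weakest missed the bound of 10 set for the test. In these 2 groups, however, only 15.05% and 17.5% of shared testis peaks had H3K27ac, against 6.35% and 8.13% of testis-only peaks. Shares this low left little room for a gap of 10 points, so the bound could not decide there. The cell content of testis also stays open and was not tested.

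H3K36me3 was almost absent from chromosome X in testis. Complete removal of the chromosome from the list does not account for it, since 13 peaks remained, but these do not exclude a partial filter. The testis list also held 1 peak on chromosome Y, against 5 in whole brain at E14.5 to 75 in liver. A single X copy does not account for the near absence on X. At least 59.3% of X genes with active promoter marks had H3K36me3 in 6 other tissue-stages, whose lists for the 3 marks were all labelled male. A lack of marked X promoters does not account for the near absence either, since 450 had H3K4me3 and H3K27ac in testis, more than in the other tissue-stages compared. A state of chromosome X in testis with marked promoters and little H3K36me3 is a hypothesis, found and tested on the same data, and the mixture of cell types in testis was not resolved.

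The H3K27me3 lists spanned 0.167 to 33.5 Mb. Scores began at 50 in the heart and liver lists, both among the 3 widest. In the other lists, whole brain at E14.5 included, they began at 1.37 (cerebellum) to 3.2 (testis). The heart and liver lists were thus scored on another scale, and whether their peaks were also called differently is not stated. Different calling sensitivity over largely shared regions cannot be told apart from differences between tissues: a median of 72.4% of the peaks of the 7 smaller lists lay in the 3 widest lists (38.8% for B cells to 81.7% for thymus, and at most 3.02% for shifted lists), between the bounds of 80 and 50 written for the test, and the read counts that would decide are not in the lists. The B-cell list as the strongest part of the regions seen in spleen cannot be told apart from a difference between B cells and spleen either: 23.1% of its peaks lay in spleen peaks, but of the strongest 1717 peaks of the other 8 lists, cut to the same width of 90 bp, 7.75% (kidney) to 63.5% (heart) did, so a low share is not particular to B cells.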

How the results depend on the processing

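Of the 12 planned tests, 11 passed the threshold. Under alternatives other than leaving out a tissue-stage, 59 of 60 values of these tests kept their direction and side, as did 174 of 174 with a tissue-stage left out. In each of these 11 tests all differences had the same sign. For the paired tests, leaving out 1 tissue-stage could therefore hardly change direction or side, and those values say little about stability. Leave-one-out ranges were 2.33 to 2.40 for the log2 ratio of peak number, 31.2 to 32.8 and 74.3 to 76.8 percentage points for H3K27ac at H3K4me3 and distal H3K27ac at H3K4me1, 0.217 to 0.251 for H3K4me3 against H3K4me1 sharing, -2.84 to -2.43 and 4.33 to 4.67 for H3K27me3 with H3K36me3 and H3K4me3, 60.8 to 64.0 points for the H3K27ac gene lists, and 72.7 to 80.4 points for developmental regulators. The exception was H3K27me3 with H3K4me3 on the stronger-scoring part of both lists, log2 1.38 (exact permutation p = 0.145); with H3K27me3 alone so filtered, an alternative chosen after seeing the data, it was 4.25. The log2 width ratio was 0.62 on the stronger-scoring part, 0.17 in lists labelled with 1 lane, 0.16 with H3K4me1 peaks joined at 1 kb (chosen after seeing the data), and -0.19 in pooled lists. The other alternatives chosen after seeing the data, namely without lists of constant width, without testis, with nearby shifts and without the widest H3K27me3 lists, are, for these 11 tests, among the 59. Ranks of the adult organ moved as follows under the stronger-scoring part, the same number of peaks and the share of peaks, in that order where each moved: heart H3K4me3 11, 10 and 7 from 9; liver H3K4me1 2, 2 and 2 from 1. Liver H3K4me3 went from 2 to 1 (same number) and 10 (share), liver H3K27ac from 3 to 4 (same number) and 2 (share), and whole brain H3K4me1 from 2 to 3 (stronger-scoring part) and 3 (share). The testis X share on the stronger-scoring part was 2.95% for H3K27ac, 3.30% for H3K4me3 (rank 9 from 19), 0.848% for H3K27me3 (rank 8 from 9), 1.15% for H3K4me1 (rank 3 from 5) and 0.0126% for H3K36me3. By covered bp it was 0.201% for H3K27me3 (rank 10), 1.77% for H3K4me1 (rank 2) and 0.00247% for H3K36me3. For each of these the cause was not tested. Of 40 named E14.5 genes none reversed and 3 went to 0 on the stronger-scoring part. Most of them had 0 bp on the lower side, where a part of the same list cannot add sequence, so these could not reverse. The genes were also picked from the same lists for large differences, so this was no test of stability. Of 70 gene list shares, 7 moved over 1.5 times, all for H3K4me3 on the stronger-scoring part: kidney 33.3%, cerebellum 54.5%, lung 30%, small intestine 41.7%, B cell 60%, granulocyte 45.5% and placenta 8.33%. Depth is unknown, so the absence of a peak does not show the absence of a mark.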

Other observations

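All lookups in this part were chosen after the data were seen, and the test of recombination sites was written after the result was seen.

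H3K9me3 in whole brain at E14.5 favoured some gene families. Of 371 numbered Zfp genes 144 (38.8%) carried a peak, and of 24 clustered protocadherins 15 (62.5%) did, against 3262 of 22367 protein-coding genes (14.6%, log2 ratio 0.59), while olfactory receptors (log2 ratio -2.02) and vomeronasal receptors (-2.29) had less than shifted lists. The widest regions held Sfi1 and Drg1 (54.6 kb covered), the gamma protocadherins (53.1 kb) and the Ugt1a genes (45.8 kb), followed by Trpm8 and the zinc finger genes Zfp146, Zfp2 and Zfp606. H3K9me3 covered 64965 bp of the clustered protocadherins in all. Much of it may therefore come from the 1 gamma region, and the 15 genes need not be separate sites. No peaks were left out for mappability, and the use of input in calling is not given, so mapping artefacts at the widest regions are not excluded. Of 797 H3K9me3 peaks in Zfp genes, 79.7% overlapped H3K36me3, against 35.9% of 6360 in other protein-coding genes and 6.52% of 6736 outside them. H3K9ac covered 91.4% of H3K4me3 peaks in heart and 95.2% in liver, and H3K79me2 had less overlap with H3K27me3 than shifted lists (log2 -1.61 in heart, -2.42 in liver).

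Joined H3K27ac peaks were widest over the following genes. Brown fat had its widest region at Pparg and Tsen2 (61.6 kb covered), macrophages at Ccl3, Ccl4, Ccl6 and Ccl9 (26.4 kb), bone marrow at Klf13, cerebellum and adult heart at Tcf4, cortex at Msra, kidney at Arhgap24, limb at Cpa1, Cpa5, Tsga14 and Mest, and adult liver at Rbm47. Olfactory bulb had it at Meis2 (71.6 kb), placenta at Fndc3b, small intestine at Gtf2e2 and Rbpms, spleen at Ubac2, Gpr18, Gpr183 and Timm8a2, testis at a cluster of Gstm genes, thymus at Rag1, Rag2 and B230118H07Rik, liver at E14.5 at a histone gene cluster, and heart and whole brain at E14.5 at Msi2. Among the 5 widest regions Tcf4 came up in 5 tissue-stages, Rbpms in 4, Gm17438 and Spnb2 in 3 each, and histone and Gimap clusters in 2 each. In testis 484 of 1281 X H3K27ac peaks (37.8%) had no overlap in another tissue-stage, against 22.6% of 33048 on the other chromosomes.

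Of the testis-only H3K4me3 peaks, 16792 (76.4%) lay far from annotated starts. At their centers CGCATGCG was found in 251 peaks against a mean of 10.5 in the flanks, and ACTTCCGG in 368 against 34. Recombination sites of meiotic cells, marked by Prdm9 at GCTGCT-type sequence, were tested as a hypothesis: GCTGCTGC was 2.79 times as frequent as in the flanks, but also 2.15 times in peaks found only in 1 other tissue-stage, so the sequence alone left the hypothesis undecided.

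The macrophage lists were labelled female and had H3K4me3 and H3K27ac peaks at 4 of 4 Y-linked genes (Ddx3y, Kdm5d, Eif2s3y and Uty) and none at the Xist promoter. The placenta lists, also labelled female, had a peak at Xist, with H3K4me3 at 0 and H3K27ac at 2 of these Y-linked genes. Among 13 H3K4me3 lists labelled male, 13 had peaks at 4 of 4, and testis alone had a peak at Xist. Among 12 H3K27ac lists labelled male, 10 had peaks at 4 of 4, bone marrow at 3 and thymus at 2, and again testis alone at Xist. Thymus was the shortest H3K27ac list (12682 peaks), though, and placenta the longest (49288 peaks). The 2 in placenta H3K27ac were thus fewer than in each male list except thymus, where the short list bears on the count.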
